A study of Homo sapiens with 6 samples.

How the data were processed

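Gene expression was measured by total RNA sequencing in HCA2 (MJ90) cells, a line of human skin fibroblasts, in 2 groups of 3 samples. The young group was uninduced cells of low passage. The senescent group had been treated with RO3306 (9 µM), an inhibitor of the kinase CDK1, and nutlin-3a (5 µM), which blocks the binding of MDM2 to p53. The labels give the treatment text on all 6 samples, so the groups were taken from the sample titles. These call the young cells uninduced and name no drug. Cells were grown in medium with 10% serum, RNA was prepared with RNeasy columns and libraries were made with the Ion Total RNA-Seq kit v2, per the labels' protocols. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

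The values deposited by the authors were raw read counts per gene, not normalised, in 3 tables that each held 1 young and 1 senescent library. Bowtie2 2.0.0, STAR 2.3.0, edgeR and R 3.2.2 and the genome builds hg19 and GRCh37 are named per the submitters' processing notes. The counting tool, the annotation and the use of strand are not given in the sources used here. Reads of a gene and an overlapping antisense gene may therefore be mixed, and reads of near-identical copies, such as ferritin, actin, histone and HLA genes and their pseudogenes, may have been split between copies or dropped. No gene positions are printed, because the annotation at hand (GENCODE release 29) belongs to a later genome build.

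The tables held 55765 gene rows and 6 count columns, all of which were used. A count in at least 1 library was present for 33986 rows. Dates stood in place of gene names in 28 rows, which were kept in library sizes and fits and are never named. Gene classes, GC content and transcript length came from GENCODE release 29 by symbol, which matched 35322 rows, older symbols included. Genes that carry information on sex, 436 in all, were left out of all tests. The endothelial marker PECAM1 was not analysed here. Total counts ranged from 6360772 to 19463280 per library, so 3 counts correspond to 0.154 to 0.472 CPM, which are counts scaled by library size. Intervals and lower bounds cover counting error only, and bounds use 3 counts over a whole group as the floor.

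The main comparison was senescent against young cells with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group, libraries were scaled by TMM, and the robust quasi-likelihood F-test was run without further covariates, two-sided, on 16411 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and rose or fell means called in that direction. The standard error (SE) of a log2 fold change was its size divided by the square root of F. Levels are given as normalised CPM, mean ± SD over 3 libraries.

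Before the data were examined, 24 gene lists and 7 lists of cell type markers were fixed from general knowledge of p53, the cell cycle, senescence and skin. Lists with at least 5 tested members, 25 in all, were tested against the other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation was run beside it, and so was fry, which tests a list against no change and not against other genes. With an estimated correlation, camera uses the few residual degrees of freedom left by 6 libraries, so its p-values are larger for that reason as well. Named genes also followed a rule set beforehand. It took 17 genes named in advance, of which 14 are reported, the 8 largest rises and the 8 largest falls among called genes with at least 10 CPM in the higher group and no overlap between groups, and members of each list. From each list came the 2 called members with the largest change in each direction and the most abundant member that was not called, and a few members that the rule picked are left out. Genes named outside this rule are said to be so.

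Each table held the young and senescent library of 1 replicate number, and the table names gave 1 sequencing run each, so the replicate number marks a shared run and pairs the samples. Deviations from the group means correlated across genes at 0.65 for the libraries of run 1, 0.05 for run 2 and 0.58 for run 3. The same fit with the run as a replicate block was therefore computed, and lowered the common biological coefficient of variation from 0.296 to 0.14. Libraries of a group were compared for duplicates. Chi-square per degree of freedom was 5.72 to 184. Because the libraries of a group came from different runs, this cannot show that the samples are separate, and they were counted as separate because the labels list them so.

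The other settings planned beforehand were RLE size factors, library size alone, no filter, a filter of at least 1 CPM in all libraries of a group, DESeq2 1.42.0, limma-voom, a fit that was not robust, a test against a fold change of 1.2, and leaving out each library in turn. Young libraries thinned to the depth of the senescent library of the same run, protein-coding genes alone, and runs 2 and 3 alone were added after the data were seen. The edgeR code was tested on simulated counts for 15974 genes with the means and library sizes of this comparison. Of 50 genes changed at each size, it recovered 0% at 1.5-fold, 8% at 2-fold, 68% at 4-fold and 90% at 8-fold. There were 3 false calls among 86, so small changes were often missed in the simulation. Far fewer genes changed there than the 4050 called in the data. Adjustment is stricter when fewer genes change, so these rates do not give the power of the real comparison.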

Results

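Total RNA of HCA2 (MJ90) human skin fibroblasts was sequenced from 3 young (uninduced) samples and from 3 samples made senescent with RO3306 and nutlin-3a. The data were raw read counts per gene. Young libraries held 19217339, 16883946 and 19463280 counts and senescent libraries 7673942, 10644680 and 6360772, so each senescent library was shallower than any young one. Protein-coding genes took 84.2% ± 1.87 of the counts in young and 76.0% ± 3.28 in senescent libraries. Short non-coding RNAs, with ribosomal RNAs included, took 11.57% ± 2.14 and 18.997% ± 3.96. Mitochondrial genes took 0.983% ± 0.076 and 1.90% ± 0.211 (SD, n = 3 each), and their transfer and ribosomal RNAs are in both shares. The design has 1 comparison, which asks how the transcripts of senescent fibroblasts differ from those of young ones. The titles call the young cells uninduced, so only the senescent group was taken to have been treated with RO3306 and nutlin-3a. Effects of senescence therefore cannot be told apart from direct effects of these drugs.

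Senescent and young libraries parted on the first principal component, which held 69.3% of the variance. The second component, with 20.8%, parted the sequencing runs in the same order in both groups. With edgeR's quasi-likelihood test, 1855 of 16411 genes rose in senescent cells and 2195 fell, and 1533 and 1791 of these changed at least 2-fold. With the run as a replicate block 8793 genes changed, 4030 up and 4763 down, among them 4018 of the 4050 called without it. Scaling by library size alone gave 1387 rises and 3127 falls (30.7% rises, against 45.8%) and moved the median log2 fold change of all genes from −0.03 to −0.24. The count of changed genes was 2192 without young replicate 2, 2056 without senescent replicate 2 and 2579 without senescent replicate 3, and that of genes changed at least 2-fold was 2162 and 2043 without the first and second of these libraries. Without the same 3 libraries in turn, falls numbered 1176, 1044 and 1318, and rises 1016 and 1012 without the first and second.

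**Figure D1:**
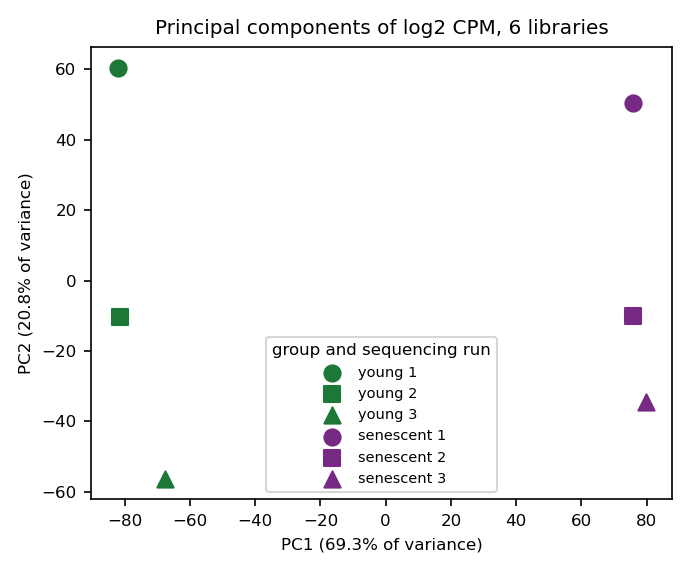
Principal components of log2 CPM in the 6 libraries, with PC1 (69.3% of variance) on the x axis and PC2 (20.8%) on the y axis; colour gives the group and the marker shape the sequencing run. Young libraries lie between −82.2 and −67.6 on PC1 and senescent ones between 75.9 and 79.7, while run 1 lies above 50 on PC2 in both groups.

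The largest rises and falls were each above 40-fold. SFRP4, a secreted modulator of Wnt signalling, went from 0.296 ± 0.333 to 181 ± 5.06 CPM (586-fold, log2 fold change 9.19 ± 0.59 SE, adjusted p = 8.5e-05, edgeR). CCND2, the G1 cyclin D2, went from 2.51 ± 0.178 to 426 ± 24.3 CPM (169-fold, 7.399 ± 0.23, adjusted p = 1.09e-05). ENPP5 rose 182-fold, NEFL (a neurofilament subunit) 122-fold, TMEM178B 83.3-fold, EHF (an ETS transcription factor) 69.8-fold, RRAGD (a Rag GTPase of the lysosomal mTORC1 pathway) 47.01-fold and ASTN1 46.0-fold. Their young counts over 3 libraries were 4, 7, 19, 11, 22 and 16 in that order, so these folds are imprecise. Among the falls, SAPCD2 and SPHKAP had 1207 and 630 young counts and none in any senescent library, which makes them at least 154-fold and 80.5-fold lower. The proliferation marker MKI67 fell 950.5-fold, the mitotic kinesin KIF20A 519.9-fold and the histone gene HIST1H3G 298-fold. These folds rest on 7, 8 and 4 senescent counts over 3 libraries, so they are imprecise. With 1 to 3 senescent counts, FAM64A was 770-fold lower (95% interval 138 to 30400), DLGAP5 686-fold (235 to 3330) and APOBEC3B, a cytidine deaminase, 317-fold (87.5 to 2620).

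Genes of mitosis and of DNA replication fell nearly as a block. Of 55 genes of G2/M and mitosis, all 55 fell, as they did adjusted over the list alone, with a median log2 fold change of −5.74 (camera adjusted p = 1.44e-123, 0.00863 with an estimated correlation). CDK1, the mitotic kinase and the target of RO3306, went from 63.3 ± 24.8 to 0.420 ± 0.376 CPM (132-fold, −7.05 ± 0.61, adjusted p = 0.000232). Of 50 genes of G1/S and DNA replication, 46 fell and 4 did not pass (47 fell and 1 rose adjusted over the list alone), with a median of −2.68 (adjusted p = 1.42e-47, 0.00755 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell 53.96-fold, and the transcriptional repressor E2F8 had 394 young counts and none in senescent cells (at least 50.4-fold lower). SLBP, which binds histone mRNA, had a log2 fold change of −0.67 ± 0.24 (adjusted p = 0.0756, 0.000359 with the replicate block and 0.0289 without young replicate 3).

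Genes of homologous recombination and the Fanconi anaemia pathway fell in 24 of 32 cases and rose in none, with 27 falls adjusted over the list alone (median −2.47, camera adjusted p = 5.67e-19, 0.0731 with an estimated correlation). The helicase gene BLM fell 49.4-fold (7 senescent counts) and RAD54L 32.4-fold (14 senescent counts), while RAD50 differed by 0.10 ± 0.31 (adjusted p = 0.845). Of 19 replication-dependent histone genes, 13 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of −3.05 (adjusted p = 2.36e-14, 0.106 with an estimated correlation). HIST1H3B fell 126-fold (25 senescent counts) and HIST1H2BM 116-fold (6 senescent counts), whereas HIST1H2AC rose 2.31-fold (adjusted p = 0.00941). HIST1H1C had a log2 fold change of −0.68 (adjusted p = 0.247, and 0.0293 with the replicate block). LMNB1, the lamin whose loss is used as a marker of senescence, fell 163-fold from 73.4 ± 9.81 CPM (10 senescent counts, −7.35 ± 0.48, adjusted p = 8.61e-05). HMGB2, a chromatin protein, fell 10.01-fold (adjusted p = 0.000236).

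**Figure D2:**
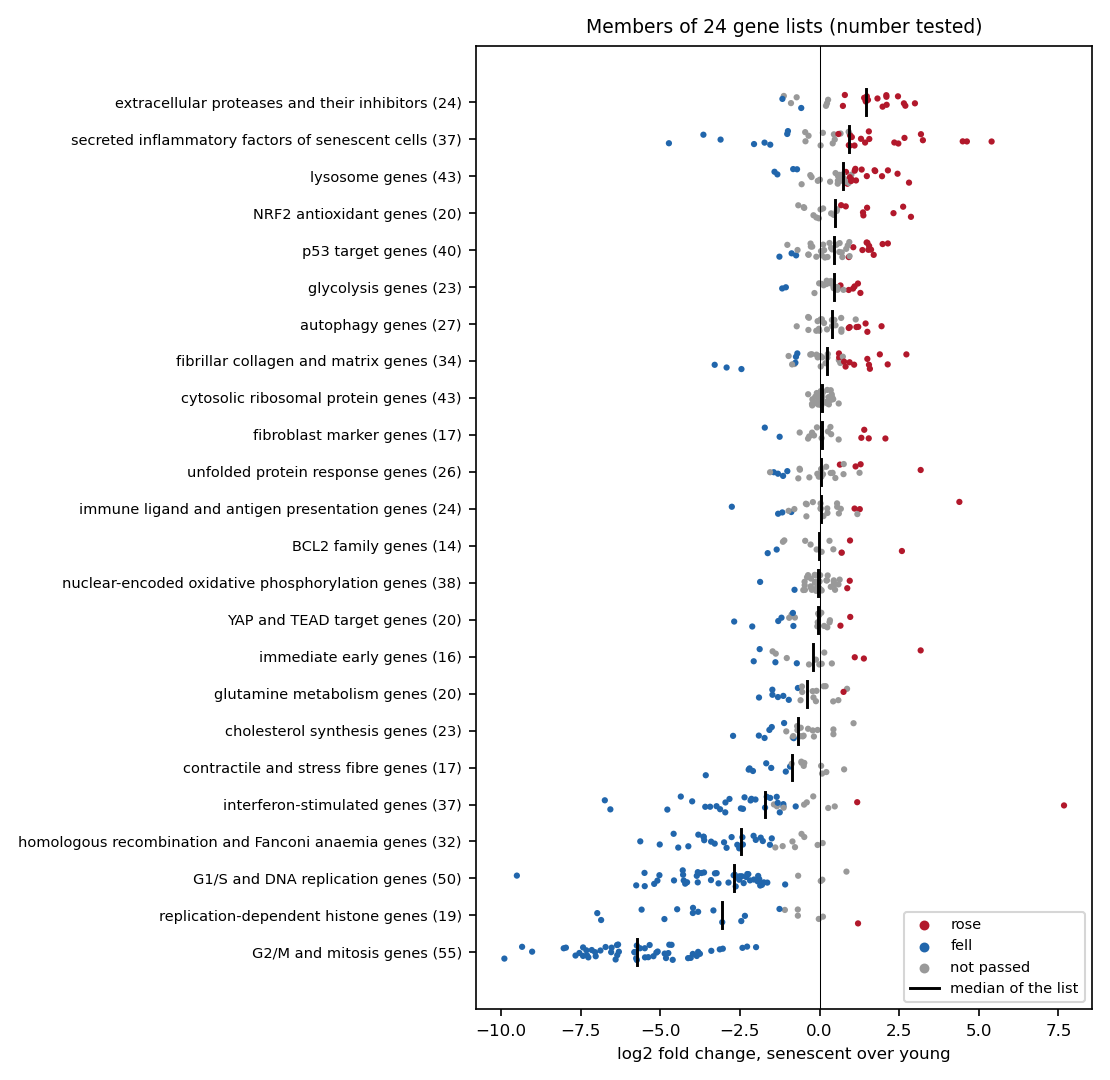
Log2 fold change (senescent over young, x axis) of each tested member of 24 gene lists (y axis, number tested in brackets), with members that rose in red, fell in blue and were not called in grey, and the list median as a black line. Medians run from −5.74 for G2/M and mitosis genes to 1.45 for extracellular proteases and their inhibitors; the fitted value of E2F8, with no senescent counts, is not a measured fold.

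Each of 3 genes of cyclin-dependent kinase inhibitors named in advance rose. CDKN1A, which encodes p21 and is a p53 target, went from 351 ± 121 to 994.5 ± 218 CPM (2.835-fold, 1.503 ± 0.31, adjusted p = 0.0104). CDKN2A, the locus of p16 and ARF, rose 4.90-fold from 6.67 ± 1.74 to 32.7 ± 3.64 CPM (adjusted p = 0.000912), and CDKN2B, which encodes p15, 2.59-fold (adjusted p = 0.00824). RB1 differed by −0.78 ± 0.40 (adjusted p = 0.189, and 0.000741 with the replicate block). Of 40 p53 target genes, 11 rose, 3 fell and 26 did not pass (16 and 4 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 0.0064, 0.0846 with an estimated correlation). GADD45A, a stress gene, rose 4.42-fold (2.15 ± 0.19, adjusted p = 0.00023), and MDM2, the ubiquitin ligase that nutlin-3a binds, 2.79-fold (adjusted p = 0.0192). The repair gene DDB2 fell 2.39-fold and the nuclease gene AEN 1.83-fold, GDF15 differed by 0.94 ± 0.56 (adjusted p = 0.258, and 0.000321 with the replicate block) and ASCC3 by 0.05 ± 0.32 (adjusted p = 0.931). With the replicate block 21 of the targets rose and 6 fell, whereas 7 rose without senescent replicate 2 and no target fell without young replicate 2 or senescent replicate 1 or 2. Without these libraries MDM2 had an adjusted p of 0.0844 (young 2), 0.0597 (senescent 1) and 0.0573 (senescent 2), and DDB2 and AEN lost their calls at 0.0543 to 0.108.

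**Figure D3:**
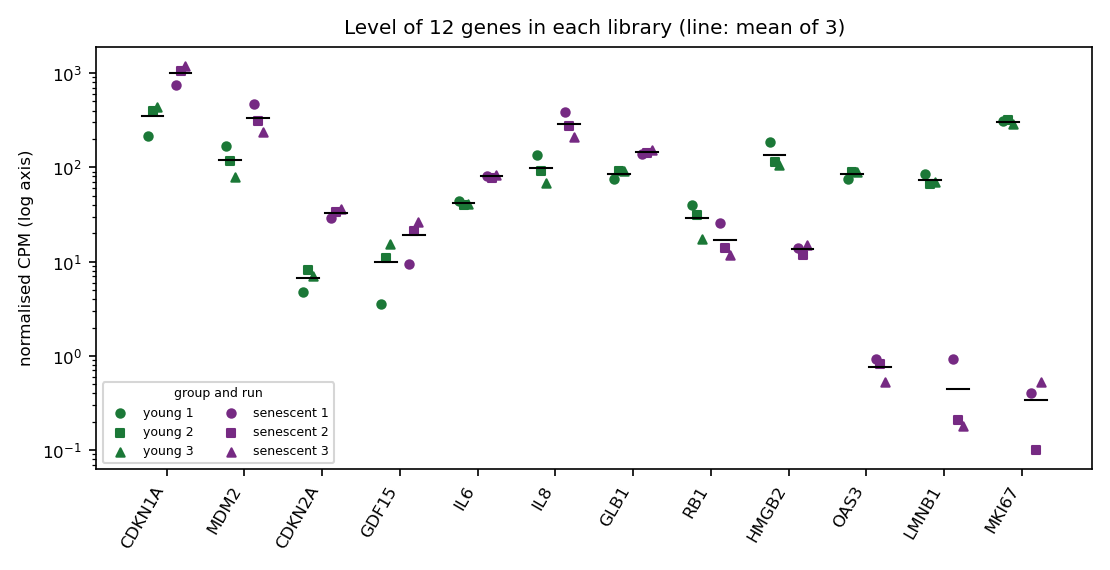
Normalised CPM (y axis, log scale) of 12 genes in each library, young in green and senescent in purple, with the marker shape giving the run and a line the mean of 3. CDKN2A lies near 6.67 CPM in young and 32.7 in senescent cells, while MKI67 goes from 305.5 to 0.344 CPM.

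Secreted inflammatory factors known from senescent cells moved both ways, with more rises than falls. Of 37 tested, 18 rose, 8 fell and 11 did not pass (19 and 8 adjusted over the list alone), with a median of 0.92 (camera adjusted p = 0.011, 0.258 with an estimated correlation). IL6 went from 41.6 ± 2.36 to 80.2 ± 3.09 CPM (1.93-fold, 0.95 ± 0.18, adjusted p = 0.00749) and the neutrophil chemokine IL8 from 98.3 ± 34.8 to 290.3 ± 86.8 CPM (2.95-fold, adjusted p = 0.0108). ANGPTL4 rose 42.3-fold and the EGF-family ligand EREG 24.7-fold. CXCL12, a chemokine of stromal cells, fell 26.5-fold from 541 ± 30.3 to 20.4 ± 1.401 CPM (adjusted p = 1.98e-05). The growth factor HGF fell 12.5-fold on 8 senescent counts. TNFRSF11B differed by −0.45 ± 0.19 (adjusted p = 0.116, and 0.00172 with the replicate block). Without young replicate 2, 10 members rose, 5 fell and IL6 and IL8 had adjusted p of 0.0546 and 0.0581. Without senescent replicate 2, 5 fell, and without young replicate 3 the list test gave 0.0941.

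Extracellular proteases and their inhibitors rose in 16 of 24 cases and fell in 2 (16 and 4 adjusted over the list alone), with a median of 1.45 (camera adjusted p = 8.19e-08, 0.0327 with an estimated correlation). The collagen-degrading cathepsin CTSK rose 7.97-fold and SERPINB2 6.47-fold, while the metalloprotease ADAMTS1 fell 2.24-fold (adjusted p = 0.00178). ADAM12 fell 1.49-fold at an adjusted p of 0.0489, and was not called without any 1 of young replicate 1 or 2 or senescent replicate 1, 2 or 3 (0.0544 to 0.198) or with RLE size factors (0.0602). Without young replicate 2 or any 1 senescent replicate, and with RLE factors or DESeq2, 1 member fell. Without a filter 14 rose and 4 fell, and with the replicate block 17 rose and 5 fell. TIMP2 differed by 0.23 ± 0.18 (adjusted p = 0.374).

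Matrix genes moved in both directions. Of 34 fibrillar collagen and matrix genes, 12 rose and 6 fell (12 and 9 adjusted over the list alone), and the list did not stand apart from other genes (median 0.22, camera adjusted p = 0.314). The proteoglycan gene LUM rose 6.62-fold from 488 ± 113 to 3231 ± 834 CPM and PLOD2, a collagen lysyl hydroxylase, 4.41-fold. ELN, which encodes elastin, fell 9.79-fold from 677 ± 248 to 69.2 ± 15.7 CPM, and the proteoglycan gene BGN 7.55-fold. THBS1 differed by 0.03 ± 0.16 (adjusted p = 0.915). Of 17 contractile and stress fibre genes, 8 fell and none rose (9 falls adjusted over the list alone), with a median of −0.87 (adjusted p = 0.0064, 0.576 with an estimated correlation). The smooth muscle actin ACTG2 was 12.8-fold lower (95% interval 4.25 to 63.0 on 3 senescent counts) and CNN1, calponin, fell 4.67-fold, with adjusted p of 0.0701 without senescent replicate 2 and 0.0509 without young replicate 2. FLNA, filamin A, differed by −0.87 ± 0.40 (adjusted p = 0.154, 0.0102 without young replicate 1 and 0.000499 with the replicate block, which gave 13 falls and 1 rise in the list). Rises among matrix genes numbered 7 without young replicate 2 or senescent replicate 2 or 3, falls 3 without those or senescent replicate 1, and contractile falls 5 without young or senescent replicate 2. With library size alone 8 matrix genes rose and 9 fell, and without a filter 10 and 9.

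Among 20 YAP and TEAD target genes, 2 rose and 6 fell (2 and 8 adjusted over the list alone), with a median of −0.06, a mean of −0.45 and a camera adjusted p of 0.0967. ANKRD1 fell 6.41-fold and the receptor kinase gene AXL 4.32-fold, IGFBP3 rose 1.95-fold and CTGF 1.58-fold, and CRIM1 differed by 0.06 ± 0.16 (adjusted p = 0.825). Of 16 immediate early genes, 3 rose and 4 fell (3 and 7 adjusted over the list alone, median −0.22, camera adjusted p = 0.612). ATF3 rose 9.03-fold and JUN 2.62-fold, EGR1 fell 4.19-fold and NR4A1 3.68-fold, and DUSP1 differed by −0.11 ± 0.19 (adjusted p = 0.694). CTGF had an adjusted p of 0.0654 to 0.113 without young replicate 2 or 3 or any 1 senescent replicate, 0.113 with library size alone and 0.147 without a filter, and JUN of 0.0547 to 0.0672 without young replicate 2 or senescent replicate 2 or 3. In the same fits 1 YAP target rose, and 1 immediate early gene rose; without senescent replicate 2, 3 YAP targets and 2 immediate early genes fell. The replicate block gave 4 rises and 9 falls among YAP targets, and 3 rises and 7 falls among immediate early genes. Without young replicate 1 or with library size alone, 7 immediate early genes also fell.

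Interferon-stimulated genes fell. Of 37 tested, 27 fell, 2 rose and 8 did not pass (29 and 2 adjusted over the list alone), with a median of −1.71 (camera adjusted p = 2.36e-14, 0.0166 with an estimated correlation) and medians of −1.76, −1.64 and −1.44 within the 3 runs. OAS3, which senses double-stranded RNA, went from 84.6 ± 8.75 to 0.764 ± 0.211 CPM (107-fold, −6.74 ± 0.30, adjusted p = 1.98e-05), and OAS1 was 114-fold lower on 1 senescent count (95% interval 20.2 to 4500.0). The chemokine gene CXCL10 was 321-fold higher on 1 young count (56.5 to 12800). TAP1 differed by −0.40 ± 0.26 (adjusted p = 0.301, and 0.0147 with the replicate block). Of 24 immune ligand and antigen presentation genes, 3 rose and 4 fell, also adjusted over the list alone (median 0.04, camera adjusted p = 0.538). The peptidase gene DPP4 rose 20.96-fold and the class I gene HLA-E 2.40-fold, while CD274, the ligand PD-L1, fell 6.74-fold from 4.92 ± 1.18 to 0.690 ± 0.395 CPM (adjusted p = 0.00358) and PDCD1LG2, PD-L2, 2.46-fold. B2M differed by 0.61 ± 0.21 (adjusted p = 0.0745, 0.0364 without young replicate 1 and 0.000203 with the replicate block, which gave 9 rises and 7 falls in the list). In this list 7 genes rose without young replicate 1, 2 fell without young replicate 2, and 1 rose and 1 fell without senescent replicate 2, where HLA-E had an adjusted p of 0.0555; PDCD1LG2 had 0.0505 to 0.0612 without young replicate 2 or senescent replicate 2 or 3.

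Lysosome genes rose in 18 of 43 cases and fell in 4 (22 and 4 adjusted over the list alone), with a median of 0.75 (camera adjusted p = 2.01e-05, 0.098 with an estimated correlation). GLB1, the gene of senescence-associated beta-galactosidase, went from 85.4 ± 8.97 to 145 ± 7.82 CPM (1.70-fold, 0.77 ± 0.19, adjusted p = 0.0193). CTSH, a cathepsin, rose 7.01-fold and FUCA1, a fucosidase, 5.46-fold, whereas the glucuronidase gene GUSB fell 2.66-fold and CLN3 2.50-fold. SCARB2 differed by 0.33 ± 0.24 (adjusted p = 0.351, and 0.0126 with the replicate block). With the block 34 members rose, whereas 10 rose without young or senescent replicate 2, and falls numbered 1 without young replicate 2 or senescent replicate 1 or 2 and 2 without senescent replicate 3. GLB1 had an adjusted p of 0.0767 to 0.0837 without young replicate 2 or senescent replicate 2 or 3, 0.059 with library size alone and 0.0597 without a filter, and CLN3 of 0.0644 to 0.0873 without young replicate 2 or senescent replicate 1 or 2.

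Autophagy genes rose in 7 of 27 cases and fell in none, also adjusted over the list alone (median 0.39, camera adjusted p = 0.0108, 0.106 with an estimated correlation). The cargo receptor gene SQSTM1 rose 3.86-fold from 683 ± 144 to 2633 ± 498 CPM (adjusted p = 0.00105) and MAP1LC3B 2.83-fold. NBR1 differed by 0.39 ± 0.21 (adjusted p = 0.22, and 0.0095 with the replicate block, which gave 14 rises and 3 falls). Of 20 NRF2 antioxidant genes, 8 rose and none fell, also adjusted over the list alone (median 0.49, adjusted p = 0.00247, 0.0846 with an estimated correlation). The ferritin genes FTH1 and FTL, which store iron, rose 7.31-fold and 6.17-fold, and reads of both can be shared with pseudogene copies. NQO1 differed by −0.10 ± 0.18 (adjusted p = 0.714). Rises among NRF2 genes numbered 4 without young replicate 2, 5 without senescent replicate 2 or 3 and 5 with library size alone. With the replicate block 11 members rose and 3 fell, and without young replicate 1 the counts were 7 and 2.

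Of 20 glutamine metabolism genes, 1 rose and 7 fell (1 and 8 adjusted over the list alone, median −0.38, camera adjusted p = 0.144). The amino acid transporter gene SLC7A5 fell 3.73-fold and CAD, of pyrimidine synthesis, 2.79-fold, while OAT rose 1.69-fold. SLC38A2 differed by −0.54 ± 0.30 (adjusted p = 0.229, and 0.000753 with the replicate block, which gave 4 rises and 10 falls in the list). Falls numbered 3 without young or senescent replicate 2, rises 2 without young replicate 1 and none without young replicate 2 or any 1 senescent replicate, and OAT kept its call among these fits only without young replicate 1 (adjusted p of 0.0591 to 0.137 without another one, 0.0876 with library size alone and 0.0542 without a filter).

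Glycolysis genes rose in 6 of 23 cases and fell in 2 (7 and 2 adjusted over the list alone), with a median of 0.45 (camera adjusted p = 0.0374, 0.576 with an estimated correlation). The glucose transporter gene SLC2A1 rose 2.31-fold (adjusted p = 0.00923) and ALDOA, aldolase, 2.43-fold, while ENO1, enolase, fell 2.25-fold and PFKP, a phosphofructokinase, 2.08-fold. GAPDH differed by 0.60 ± 0.28 (adjusted p = 0.155, and 0.000263 with the replicate block, which gave 14 rises). The list test gave 0.131 without young replicate 1, 0.057 and 0.0964 without senescent replicate 2 and 3 and 0.0602 with library size alone. Without young or senescent replicate 2, 3 genes rose and none fell, and 1 fell without young replicate 3 or senescent replicate 1 or 3. In such fits ALDOA had an adjusted p of up to 0.0881, ENO1 of up to 0.0634 and PFKP of up to 0.106.

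Of 38 nuclear-encoded oxidative phosphorylation genes, 2 rose and 2 fell, with none adjusted over the list alone (median −0.05, mean −0.02, camera direction up, adjusted p = 0.824). At an unadjusted p under 0.05, 5 were higher and 3 lower, DESeq2 called 2 rises and 1 fall and limma-voom 1 and 1. COX4I1 rose 1.93-fold and NDUFA2 1.83-fold, and ATP5B differed by −0.11 ± 0.17 (adjusted p = 0.675). NDUFV2 fell 3.64-fold on 10 senescent counts and NDUFA9 1.72-fold. None of the 38 was called without young replicate 2 or senescent replicate 2 or 3, 1 fell and none rose without young replicate 1, and none fell without senescent replicate 1, whereas the replicate block gave 9 rises and 9 falls, and library size alone none and 4. With young libraries thinned to senescent depth 2 rose and none fell (NDUFA9 at 0.0503, NDUFV2 below the filter), and among protein-coding genes alone 4 and none (NDUFA9 at 0.0587, NDUFV2 at 0.0521). NDUFV2 was also below the filter without young replicate 1 or 2. Those of the 4 genes that lost their call in these fits had adjusted p of 0.0523 (NDUFA2) to 0.175 (COX4I1).

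Cholesterol synthesis genes fell in 7 of 23 cases and rose in none (8 falls adjusted over the list alone), with a median of −0.69 (camera adjusted p = 0.00769, 0.148 with an estimated correlation). INSIG1, which restrains sterol synthesis, fell 3.75-fold (adjusted p = 0.00267), and LSS differed by 0.44 ± 0.32 (adjusted p = 0.35, and 0.00552 with the replicate block, which gave 15 falls and 3 rises). Falls numbered 3 without young or senescent replicate 2 and 4 without senescent replicate 1 or 3. Of 26 unfolded protein response genes, 4 rose and 4 fell (6 and 8 adjusted over the list alone, median 0.06, adjusted p = 0.612). ATF3 rose 9.03-fold and DDIT3, which encodes CHOP, 2.45-fold, while ASNS, asparagine synthetase, fell 2.47-fold and CHAC1 2.71-fold. CALR differed by −0.02 ± 0.23 (adjusted p = 0.954). In this list 7 rose and 7 fell without young replicate 1, 2 fell without young or senescent replicate 2, 8 fell with library size alone, and the replicate block gave 10 and 9. CHAC1 had an adjusted p of 0.0524 to 0.148 without any 1 library other than young replicate 1 and of 0.0678 with limma-voom.

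Cytosolic ribosomal protein genes did not move as a list. None of 43 was called, also adjusted over the list alone, by edgeR, DESeq2 or limma-voom, and 1 was higher at an unadjusted p under 0.05 (median 0.08, camera adjusted p = 0.428). With the replicate block 11 rose and 1 fell, and 1 rose without young replicate 3. RPLP0 differed by −0.03 ± 0.22 (adjusted p = 0.929). Of 14 BCL2 family genes, which regulate apoptosis, 3 rose and 2 fell, also adjusted over the list alone (median −0.01, adjusted p = 0.892). HRK rose 6.003-fold on 11 young and 26 senescent counts, and BID rose 1.94-fold. BCL2 fell 3.09-fold on 16 senescent counts and BOK 2.54-fold, and MCL1 differed by −0.09 ± 0.27 (adjusted p = 0.836). No member rose without young replicate 2 or senescent replicate 2 or 3 (HRK and BID at 0.0554 to 0.0927), none fell without senescent replicate 2 or 3 and 1 fell without young replicate 2 or senescent replicate 1 (BCL2 and BOK at up to 0.0916), the replicate block gave 5 rises and 5 falls, and library size alone 2 and 3.

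Of 17 fibroblast marker genes, 4 rose and 2 fell, also adjusted over the list alone (median 0.07, camera adjusted p = 0.485). MME rose 4.19-fold and TWIST2 2.92-fold, TCF21 fell 3.29-fold and the receptor gene PDGFRB 2.38-fold, and VIM, vimentin, differed by −0.32 ± 0.16 (adjusted p = 0.177, and 0.0117 with the replicate block, which gave 8 rises and 5 falls). Without young or senescent replicate 2, 2 rose and 1 fell, and TWIST2 and PDGFRB had adjusted p of up to 0.0965 and 0.0624; without senescent replicate 3 TWIST2 had 0.0927. All 8 smooth muscle and pericyte markers were tested; CSPG4 fell 3.08-fold and SMTN 2.65-fold, also adjusted over the list alone, and the list did not stand apart (median 0.24, mean −0.08, adjusted p = 0.96). MCAM differed by 0.39 ± 0.22 (adjusted p = 0.242, and 0.00668 with the replicate block, which gave 2 rises and 2 falls in the list). Without young replicate 2 neither CSPG4 nor SMTN was called (0.0605 and 0.112), and SMTN had 0.0591 to 0.0911 without young replicate 3 or any 1 senescent replicate 0.0533 with limma-voom and 0.0511 among protein-coding genes alone. Without senescent replicate 1 another marker rose.

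Markers of other cell types were mostly near the floor. Red blood cell genes reached at most 0.032 CPM in young and 0.178 in senescent cells, and leukocyte markers 1.11 and 2.29 CPM. Of 3 leukocyte markers tested, CD14 was 7.67-fold lower (95% interval 2.50 to 38.2 on 3 senescent counts, adjusted p = 0.0173) and TYROBP differed by 1.55 ± 0.55 (adjusted p = 0.0743, and 0.0166 with the replicate block). Of 2 endothelial markers tested, TEK fell 8.99-fold and EGFL7 rose 4.48-fold, and of 2 adipocyte markers LEP, leptin, rose 15.03-fold from 0.107 to 1.67 CPM and PPARG differed by −0.39 ± 0.24 (adjusted p = 0.28). None of 4 keratinocyte and 2 melanocyte markers was called by edgeR or passed an unadjusted p under 0.05. Adjusted over the list alone, 1 leukocyte marker rose and 1 fell, 1 endothelial marker rose and 1 fell, 1 adipocyte marker rose and no keratinocyte or melanocyte marker was called. With the replicate block 1 rose in each of the keratinocyte and melanocyte lists, as 1 keratinocyte marker did without young replicate 1, and MITF, at 38.1 CPM in young cells, had an adjusted p of 0.0429. DSP, a desmosome gene, had 96.6 ± 16.9 CPM in young and 91.4 ± 5.27 in senescent cells. CD14 had an adjusted p of 0.0589 to 0.0615 without young replicate 2 or senescent replicate 2 or 3, and EGFL7 of 0.0504 without senescent replicate 3. With young libraries thinned to senescent depth, CD14 and LEP did not pass the filter and were not tested.

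The runs differed within each group along GC content. Across 14632 genes with a GC value (89.2% of those tested), the log2 difference of run 1 minus run 3 had a Spearman's rho with GC of −0.77 in young and −0.72 in senescent libraries, and the senescent over young log2 fold change one of −0.08. Genes are not independent replicates, so no p is given. Genes of 35 to 40% GC had a median run difference of 1.10 in young and 0.83 in senescent libraries, and genes of 60 to 65% GC of −1.05 and −0.71, where the median group difference was −0.08 and −0.33.

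**Figure D4:**
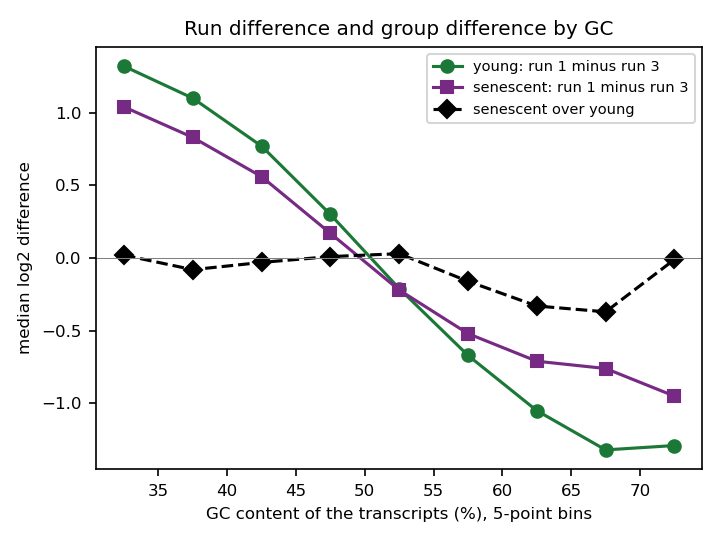
Median log2 difference (y axis) of genes in bins of 5 percentage points of GC content (x axis), for run 1 minus run 3 in young (green) and senescent (purple) libraries and for senescent over young (black, dashed). The run difference goes from 1.32 to −1.29 in young libraries, and the group difference stays between −0.37 and 0.03.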

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

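Thinned young libraries, protein-coding genes alone, and runs 2 and 3 alone were chosen after seeing the data. Direction held in nearly all comparisons of named genes. Over 132 named genes and all settings, 2036 of 2235 values kept direction and side of the threshold, 128 lost the call, 37 gained it and 34 changed sign. Depth limits the senescent group, where 3 counts are up to 0.472 CPM. The causes of the changes below were not tested. Leaving out libraries leaves fewer samples, but this cannot be the only cause. The count of changed genes rose from 4050 to 5047 without young replicate 1 and to 4564 without young replicate 3. With runs 2 and 3 alone it was 5837. On the second principal component, which parted the runs, replicate 2 (−10.4 in young, −10 in senescent) lay between replicates 1 and 3 in both groups.

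With the replicate block the changed genes numbered 8793, with 4030 rises and 4763 falls. The block ended or added no list call at the preset correlation, and changed no other call of a named gene than those given beside the results. With both the block and an estimated correlation the lowest camera adjusted p of a list was 0.234. G2/M genes, all 55 of which fell with the block, had this value too. So few residual degrees of freedom are left with the block that this form cannot tell whether a list stands apart. Leaving out 1 library gave 2056 to 5047 changed genes, 1012 to 2283 rises, 1044 to 2845 falls and 2043 to 3967 genes changed at least 2-fold. The 14 lists called at the preset correlation became 4 with an estimated one (G1/S, G2/M, proteases and interferon-stimulated genes). Among the others, camera adjusted p was 0.0846 for p53 targets, 0.0731 for homologous recombination, 0.106 for histones, 0.258 for inflammatory factors and 0.098 for lysosome genes. It was 0.576 for contractile genes, 0.576 for glycolysis, 0.148 for cholesterol, 0.0846 for NRF2 and 0.106 for autophagy genes. The estimated correlation was −0.012 for p53 targets, −0.042 for NRF2 and 0.005 for autophagy genes, none above the preset 0.01. For these lists the loss of the call was therefore not due to a higher correlation.

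Without 1 library, list adjusted p ranged from 0.00485 to 0.0941 for inflammatory factors, 0.00864 to 0.131 for glycolysis, 0.8 to 0.993 for the BCL2 family and 0.657 to 0.979 for smooth muscle markers, the last 2 with changes of direction. Glycolysis had 0.0602 with library size alone. Without a filter, YAP targets had 0.00564, glutamine genes 0.0131, oxidative phosphorylation 0.859 and the BCL2 family 0.859, the last 2 reversed. Fry, which tests a list against no change and not against other genes, gave 0.00484 for YAP targets, 0.00274 for glutamine genes, 0.0261 for fibroblast markers and 0.0637 for glycolysis. The BCL2 family also reversed with thinned libraries (0.956), and smooth muscle markers with protein-coding genes alone (0.843).

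All genes that changed sign were uncalled, with main log2 fold changes near 0. With library size alone these were ASCC3 (−0.15), RAD50 (−0.099), THBS1 (−0.184) and CRIM1 (−0.152), without a filter ASCC3 (−0.049), THBS1 (−0.067) and CRIM1 (−0.039), and with RLE factors CALR (0.005). Thinning gave CALR 0.001 and RPLP0 0.006. Protein-coding genes alone gave ATP5B 0.022, CALR 0.104, NQO1 0.033, MCL1 0.048, RPLP0 0.096, DUSP1 0.022 and DSP 0.058, and runs 2 and 3 alone MCL1 0.03, DUSP1 0.045 and DSP 0.058. Without 1 library the ranges were −0.194 to 0.351 for ASCC3, −0.121 to 0.419 for RAD50, −0.001 to 0.106 for THBS1, −0.189 to 0.139 for CALR, −0.157 to 0.004 for NQO1, −0.27 to 0.17 for MCL1, −0.184 to 0.123 for RPLP0 and −0.2 to 0.052 for DSP.

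Calls of named genes also moved under settings other than leaving out libraries and the block. ADAM12 lost its call without a filter (0.0547), with DESeq2 (0.0519), RLE factors (0.0602), thinning (0.0501) and protein-coding genes alone (0.0731). CHAC1 had 0.0678 with limma-voom, 0.0597 with thinning and 0.0647 among protein-coding genes, where PFKP had 0.0541 and SMTN 0.0511. NDUFA9 had 0.0508 without a filter, 0.0503 with thinning, 0.0587 among protein-coding genes and 0.0707 in runs 2 and 3. NDUFV2 had 0.0505 with RLE factors, 0.0586 with DESeq2, 0.106 with limma-voom, 0.0521 among protein-coding genes and 0.112 in runs 2 and 3. COX4I1 had 0.0866 and NDUFA2 0.0825 with library size alone, and COX4I1 0.0635 with limma-voom. Below the filter, and so not tested, were ACTG2, NDUFV2, HRK, CD14 and LEP with thinned libraries, and NDUFV2 and HRK with the stricter filter.

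Calls were gained without a filter by RB1 (0.0262), FLNA (0.000304), HIST1H1C (0.0222), SLBP (0.0343), SLC38A2 (0.0455) and TYROBP (0.0347), and with library size alone by SLBP (0.0334), TNFRSF11B (0.044) and VIM (0.0352). Protein-coding genes alone added B2M (0.0212) and TYROBP (0.0429). Runs 2 and 3 alone added GDF15 (0.0358), TNFRSF11B (0.0289), TAP1 (0.0449), FLNA (0.00299), GAPDH (0.0112) and B2M (0.017).

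In 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, 4050 genes were called by edgeR, 3324 of them at least 2-fold. The highest other split called 0 and 0, with up to 2213 genes at an unadjusted p under 0.05. The real split called 14 lists and the highest other 13, in a split of young replicates 1 and 3 with senescent replicate 2 against the rest. With 10 splits no share under 0.05 is possible. Every other split mixed young and senescent libraries, so the group difference became spread within each set and few gene calls were possible. Each also kept part of the group difference, so lists could still be called. The splits ignored the pairing of libraries by run. They therefore cannot tell how many calls would arise without a group difference.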

Other observations

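The genes and gene groups named in this part were chosen after their values were seen. Small nucleolar RNAs, which guide the modification of ribosomal and other RNAs, rose in 125 of 191 cases and fell in none (median log2 fold change 1.72, edgeR); with library size alone 115 rose and 2 fell. Members of the imprinted clusters were among them. Of 23 SNORD116 genes 20 rose (median 3.19), of 7 SNORD113 genes 6 (2.83) and of 16 SNORD114 genes 12 (1.84). The 5 SNORD115 genes tested had 1 count in young and 141 in senescent libraries, a 368-fold higher level (95% interval 64.9 to 14600). Their host transcript SNHG14 rose 2.72-fold (adjusted p = 0.00376) and MEG8, of the SNORD113 and SNORD114 cluster, 3.45-fold (adjusted p = 0.0343), while MEG3 of the same cluster differed by −0.35 ± 0.21 (adjusted p = 0.267). SNORA77 rose 21.3-fold. Of 65 microRNA genes 40 rose and none fell. Without a filter the counts were 45 and 7 of 500, with a median of −1.52, and 29 rose without young or senescent replicate 2. Counts per gene do not tell whether these reads came from mature microRNAs or from longer transcripts. RN7SK and RMRP, abundant short RNAs, differed by −0.02 ± 0.20 and 0.03 ± 0.42.

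Among other genes outside the lists, TXNIP, a regulator of glucose uptake, rose 22.8-fold from 33.99 ± 4.01 to 773.8 ± 46.7 CPM (adjusted p = 1.98e-05). The complement gene C3 rose 18.5-fold from 28.1 ± 6.26 to 519 ± 84.1 CPM and SOD2, the mitochondrial superoxide dismutase, 17.4-fold from 254 ± 46.2 to 4425 ± 760.3 CPM. Mitochondrial transfer RNAs rose in 17 of 21 cases and mitochondrial mRNAs in 8 of 13, against 11 and 5 without young replicate 2. Of 19 ferritin genes and pseudogene copies, which share reads, all 19 rose. Of 32 actin and tubulin genes 13 fell and none rose, ACTB 2.39-fold and TUBA1B 3.76-fold, whereas 7 fell without senescent replicate 2.

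The tests of a gain of all short RNAs, the microRNA and transfer RNA comparisons included, of host transcripts and of leukocyte loss were chosen after the results were seen. Run 1 and run 3 differed in the same genes in young and senescent cells. The difference followed GC content, with Spearman's rho of −0.77 in young and −0.72 in senescent libraries, and followed transcript length weakly, with 0.13 and 0.12. A step of library preparation or sequencing that acts on GC content may therefore lie behind the run difference. Length lay between the bounds set beforehand, so its part cannot be told apart. Because each run held 1 library of each group, the runs are balanced over the comparison. The run difference was larger in young than in senescent libraries in most GC bins, so it need not cancel. At 35 to 40% GC it was 1.10 against 0.83, and at 60 to 65% −1.05 against −0.71. A part linked to GC in the group difference therefore stays open. The run difference also adds to the spread within groups (common biological coefficient of variation 0.296, and 0.14 with the replicate block).

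The median log2 fold change of all 191 small nucleolar RNAs tested, 66 of which were not called, was 1.72; as a group they had no test against other genes. Small nucleolar RNAs were not matched to their own hosts, and genes are not independent replicates. A comparison with host transcripts therefore cannot tell whether a rise of the hosts is the whole cause. The median of small nucleolar RNAs lay 0.99 above that of 20 non-coding host transcripts (0.73), with a 95% bootstrap interval over genes of 0.52 to 1.32. It lay 0.83 above that of 27 other short RNAs (0.48 to 1.48; the others had 0.88), but −0.19 (−0.76 to 0.48) from that of 65 microRNAs past the filter, with a median of 1.91 (1.31 over 131 with DESeq2 and −1.52 over 500 without a filter, most of which lay below the filter, against 1.78 and 1.57 for small nucleolar RNAs), and 0.13 (−0.39 to 0.53) from that of mitochondrial transfer RNAs, with 1.58. A gain of short RNAs in the senescent libraries therefore stays open. How well the RNeasy columns kept short RNAs in each group was not tested. Better capture of the shortest ones was judged by the rho of length and log2 fold change across 187 small nucleolar RNAs. Its value of −0.05 lay on the side of the bound set beforehand that speaks against such capture. An interval was not part of that rule. The interval of −0.18 to 0.09 spans the bound, so better capture is not settled. A slower turnover of these RNAs in senescent cells was not tested.

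Interferon-stimulated genes fell in senescent cells. With young libraries thinned to senescent depth, 26 members fell, against 27 with full libraries. Leaving out 1 library gave from 19 falls (young or senescent replicate 2) to 28 (young replicate 3). The highest leukocyte marker in young cells had 1.11 CPM, against a median of 26.5 CPM for the fallen members, which argues against a loss of leukocytes. Whether the young cultures had an interferon response of their own stays open.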
